A study of Mus musculus with 8 samples.

How the data were processed

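Total RNA from 8 primary mammary tumours of transgenic FVB mice was measured on Affymetrix whole-transcript expression arrays, 1 array per tumour. The genotype given in the sample labels placed 4 tumours in the NeuNT group and 4 in the NeuNT/H1074R group. The series title writes the p110α mutation as H1047R and the sample labels write it as H1074R, so the group is named here as in the labels. The tumours were numbered 1 to 4 within each group, and the tumour numbers in the labels are not shared between groups. The labels do not state whether the tumours came from separate mice or when the arrays were run.

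The authors deposited 1 table of log2 values, with a column for each tumour and 41345 probes. Per the submitters' processing notes, the Affymetrix Expression Console and the Transcriptome Analysis Console were used; versions, the background correction and the normalization are not given in the sources used here. The log2 scale was taken from the deposited values, which ran from 0.887 to 13.6. The array medians lay between 4.82 and 4.87, so the arrays were used as deposited, without further scaling. Array values carry no read depth, and the number of arrays limits the precision. Over the tested genes the median residual SD between tumours of a genotype was 0.248 on the log2 scale, and the median 95% interval of a difference between genotypes reached 0.395 to either side.

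Probes were named from the platform annotation. It listed 23521 probes with 1 gene symbol and 1814 with several, and the other 16010 were not listed and stay unnamed here. Entrez identifiers of 23328 of the named probes were found in the mouse RefSeq annotation (assembly GRCm38.p6), 193 were not found, and 0 symbols had to be updated. The build used to design the array is not given in the sources used here, so the annotation served only for names and for the order of neighbouring genes. Probes with several symbols were left out. Of the 22180 genes with a probe of their own, 1082 had several probes and were represented by the probe with the highest mean over the 8 tumours. Genes with a mean in the lowest 25% of genes, under 4.06, were left out as dim, which removed 5545 genes and left 16635 for testing.

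Differences between genotypes were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with no covariate, as NeuNT/H1074R minus NeuNT. The tests were two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Before the data were examined, 40 gene lists were fixed: pathways downstream of ErbB2 and PI3K, metabolic and stress programmes, mammary epithelial states, and markers of cell types a tumour can hold. Of these, 39 had at least 5 tested members, and the red blood cell genes did not. The lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 39 lists. Camera with a correlation estimated for each list, fry, and an exact two-sided permutation test of the list mean per tumour were run beside it. An exact test of 4 tumours against 4 cannot give a two-sided p below 0.0286. Structure among the tumours was described by Pearson correlations over the tested genes, principal components and the share of variance between genotypes.

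The rule for naming genes was also fixed before the data were examined. It takes Erbb2 and Pik3ca, up to 12 genes per direction past the threshold with groups that do not overlap, and up to 4 members of smallest unadjusted p for each list described. Where fewer than 5 genes in a direction pass, those of smallest unadjusted p are added up to 5 and given as values that did not pass. Predicted or clone names (Gm with digits, endings in Rik, starts with LOC, Mir or Snor) and olfactory or vomeronasal receptors were counted but not named. Other named genes were chosen after their values were seen, and are described as such.

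The gene and list tests were checked on data simulated for this comparison of 4 against 4 over 16635 genes, with 200 genes changed, in 20 runs. On average 18.2% of genes changed 1.5-fold were recovered, 54.2% of those changed 2-fold, 85.2% of those changed 4-fold and 94.4% of those changed 8-fold, with 6.6 false calls per run. Lists shifted by 0.5 on the log2 scale were recovered in 100% of cases, with 0.45 false lists per run, for simulated genes that vary independently of one another.

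The alternatives left out each tumour in turn, normalized the arrays again by quantiles, centred them on their medians, removed the filter on dim genes or raised it to the lower 50%, averaged all probes of a gene, and changed the variance model or weighted the arrays. For the gene count, every probe was also tested under its own identifier, and an ordinary two-sample test with equal variances replaced limma's moderated one. A fit without both tumours with high muscle genes, and camera's estimated correlation with each tumour left out, were added after the data had been seen. Plots were drawn with matplotlib 3.10.9.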

Results

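Gene expression was measured in 8 primary mammary tumours from transgenic mice of the inbred FVB strain. All carried NeuNT; Neu is the rodent name of the receptor tyrosine kinase ErbB2. In 4 tumours this was the only modification named, and 4 tumours, labelled NeuNT/H1074R, also carried a mutation of p110α, the catalytic subunit of phosphoinositide 3-kinase (PI3K) encoded by Pik3ca. The single comparison of the design asks how ErbB2-positive tumours with mutant p110α differ in gene expression from those with wild-type p110α. The values are log2 array signals, with medians from 4.82 to 4.87 across the arrays. Because the labels do not state that the tumours came from separate mice, p-values measure the spread between these tumours.

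Tumours with mutant p110α had on average lower transcripts of mast cell, adipocyte, macrophage and fibroblast markers, of MHC class II and chemokine genes, and of milk proteins. They had higher transcripts of skeletal muscle genes, with a list mean above all NeuNT tumours in 2 of the 4. The best known genes downstream of PI3K did not separate the genotypes, and neither did Erbb2 or Pik3ca. Single tumours stood apart by a squamous and hair keratin programme or by basal genes, and blocks of genes beside Erbb2 differed from tumour to tumour. No single gene passed the test, and each shift of a gene list was lost once the correlation between its genes was estimated from these tumours.

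Erbb2, the receptor behind both models, had a log2 value of 9.27 ± 0.26 (SD, n = 4) in NeuNT/H1074R tumours and 9.50 ± 0.71 (SD, n = 4) in NeuNT tumours. The log2 difference of −0.23 ± 0.33 (SE) did not pass (limma, adjusted p = 0.978). Its spread was wide among NeuNT tumours, from 8.73 in replicate 2 to 10.28 in replicate 1, and without NeuNT replicate 1 the difference turned to 0.03, while without NeuNT replicate 2 it was −0.49. Pik3ca stood at 8.20 ± 0.11 (SD, n = 4) in NeuNT/H1074R and 8.28 ± 0.06 (SD, n = 4) in NeuNT tumours, a log2 difference of −0.08 ± 0.11 (SE) that did not pass either (limma, adjusted p = 0.978). The Pik3ca difference ran from −0.13 to −0.05 without NeuNT/H1074R replicates 1 and 3 in turn, and was −0.03 with quantile normalization and with centred arrays. How far the probes read the transgene transcripts, or tell a mutant transcript from the wild type, is not known from the labels, so neither gene checks the genotypes.

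**Figure D1:**
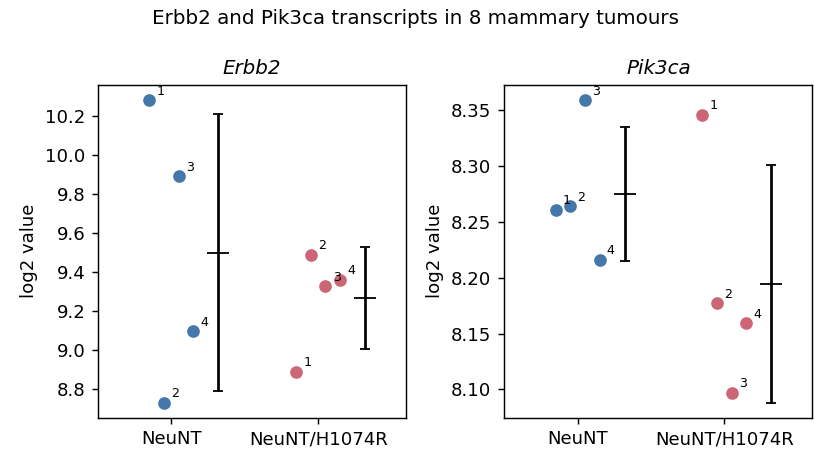
Log2 values of Erbb2 (left) and Pik3ca (right) in each tumour, on separate axes that do not start at 0, with points numbered by replicate and bars giving the mean ± SD of the 4 tumours of a genotype. Erbb2 ranged from 8.73 to 10.28 in NeuNT and from 8.89 to 9.49 in NeuNT/H1074R tumours, and both genes overlapped between genotypes.

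Among the 16635 genes tested, 0 passed the threshold in limma, where 635 had an unadjusted p under 0.05 (351 higher and 284 lower in NeuNT/H1074R) and 832 would be expected by chance. An ordinary two-sample test with equal variances also gave 0 genes after adjustment, with 714 at an unadjusted p under 0.05. A test of all 31009 probes that passed the same filter gave 0, with 1600 at an unadjusted p under 0.05. The smallest adjusted p, 0.572, belonged to Zfp185, a LIM domain protein gene, which was lower by a log2 difference of −1.30 ± 0.17 (SE) and lay below every NeuNT tumour in all 4 NeuNT/H1074R tumours. The other genes of smallest p also had groups that did not overlap, and none passed (limma, adjusted p = 0.978). Vegfd, a growth factor for lymphatic vessels, had a log2 difference of −1.09 ± 0.25 (SE), Tmem159 of −1.34 ± 0.32 (SE), AW047730 of −0.51 and Olfm5 of −0.45. Values were higher in NeuNT/H1074R for Gramd1b (0.98), for Mybpc2, a myosin-binding protein of fast skeletal muscle (0.93), for Ormdl3, a regulator of sphingolipid synthesis that neighbours Erbb2 (0.67), for Fsip1 (0.47) and for Pgpep1l (0.44). The values of the genotypes did not overlap for 447 genes, or 2.69% of those tested, against 2.86% by chance.

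Of the 39 gene lists, 12 passed camera with the preset correlation, 2 higher and 10 lower in NeuNT/H1074R. None of the 12 held with an estimated correlation (smallest adjusted p = 0.804), in fry (smallest adjusted p = 0.690) or in the exact permutation of the list means (smallest adjusted p = 0.902). At an unadjusted p under 0.05 these gave 1, 2 and 0 of the 39 lists. The estimated correlation between members had a median of 0.265 over the lists and reached 0.773 in the cell cycle list. In every list 0 members passed over all genes tested. Adjusted over the list alone, 2 mast cell markers passed, and 0 members of the other 11 called lists. That adjustment takes no account of the 39 lists tried, so members of some lists can pass by chance.

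Mast cell markers had the largest mean difference among the called lists. All 8 tested members, of 12 in the list, were lower in NeuNT/H1074R tumours, with a mean log2 difference of −0.90 (camera adjusted p = 4.2e-05, and adjusted p = 0.804 with an estimated correlation). The mast cell protease Mcpt4 differed by −2.13 ± 0.60 (SE), the tryptase Tpsb2 by −1.05 ± 0.31 (SE), carboxypeptidase Cpa3 by −2.08 ± 0.72 (SE) and the chymase Cma1 by −0.66 ± 0.25 (SE). Log2 signals in NeuNT/H1074R tumours were low for Mcpt4 (1.87 to 4.35) and Cma1 (4.16 to 4.39). Genes with a mean under 4.06 had been left out as dim, so the sizes of the Mcpt4 and Cma1 differences are uncertain. In the same tumours Tpsb2 ran from 4.64 to 5.22 and Cpa3 from 3.68 to 6.21. Mcpt4 and Tpsb2 passed when adjusted over the list alone (limma, adjusted p = 0.0348 for both). One NeuNT tumour, replicate 3, lay with the other genotype, with a list mean of −0.34 against 0.68 to 0.76 in the remaining NeuNT tumours and −0.98 to −0.11 in NeuNT/H1074R. The camera call held whichever tumour was left out, with means from −1.17 to −0.73. With no filter on dim genes the mean was −0.60, so the members left out as dim were not all lower.

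Markers of fat and connective tissue were lower as well. Of the adipocyte markers, 17 of 18 were lower, by −0.47 on average (camera adjusted p = 0.00044; adjusted p = 0.804 with an estimated correlation), including the fatty acid carrier Fabp4 (−1.12 ± 0.47 SE), the lipid droplet genes Plin4 (−0.84) and Cidec (−1.19), and Lgals12 (−0.59). Of the fibroblast and matrix markers, 24 of 29 were lower, by −0.27 on average (camera adjusted p = 0.0132; adjusted p = 0.834 with an estimated correlation), among them the matrix genes Dpt (−1.56 ± 0.67 SE) and Dcn (−1.07 ± 0.55 SE), Serpinf1 (−0.68) and Cd34 (−0.37). The adipocyte call was lost without NeuNT replicate 2 (−0.29, camera adjusted p = 0.052), and the mean was −0.30 without NeuNT replicate 1 (camera adjusted p = 0.0242). The fibroblast call was lost without NeuNT replicate 2 (−0.11), NeuNT replicate 3 (−0.22), NeuNT/H1074R replicate 3 (−0.19) or NeuNT/H1074R replicate 4 (−0.16), and with array weights (−0.22), while the mean was −0.49 without NeuNT replicate 4. Without NeuNT replicate 2, Dcn stood at −0.53, Serpinf1 at −0.40, Cd34 at −0.21 and Plin4 at −0.51, and without NeuNT replicate 1 Cidec stood at −0.72.

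Inflammatory and antigen presentation genes followed the same direction. Chemokines and inflammatory cytokines were lower for 26 of 29 members, by −0.44 on average (camera adjusted p = 0.00129; adjusted p = 0.804 with an estimated correlation), with the stromal chemokine Cxcl12 at −0.88 ± 0.36 (SE), Ccl6 at −0.93, the eotaxin Ccl11 at −0.64 and, against the trend, Ccl20 at 0.34. Macrophage and monocyte markers were lower for 24 of 29 members, by −0.29 on average (camera adjusted p = 0.0023; adjusted p = 0.834 with an estimated correlation), with Folr2 at −0.87, Ly6c2 at −0.82, Lyz1 at −0.50 and Ccr2 at −0.47. MHC class II genes were lower for 7 of 8 members, by −0.38 on average (camera adjusted p = 0.0108; adjusted p = 0.804 with an estimated correlation). They included H2-Ab1 (−0.71 ± 0.38 SE), the peptide loading genes H2-DMa (−0.60) and H2-DMb2 (−0.46), and their transcriptional activator Ciita (−0.36). The chemokine call was lost without NeuNT replicate 4 (−0.24), the macrophage call without NeuNT replicate 3 (−0.21) or NeuNT/H1074R replicate 3 (−0.14), and the MHC class II call without NeuNT replicate 2 (−0.30), NeuNT replicate 4 (−0.30) or NeuNT/H1074R replicate 3 (−0.20). Without NeuNT/H1074R replicate 3, H2-Ab1 stood at −0.35, H2-DMa at −0.39, Ciita at −0.23 and Ccr2 at −0.29. Ccr2 stood at −0.30 without NeuNT/H1074R replicate 4 and −0.71 without NeuNT/H1074R replicate 2, Ccl11 at −0.36 without NeuNT/H1074R replicate 4, Cxcl12 at −0.56 without NeuNT replicate 2 and Ly6c2 at −1.28 without NeuNT replicate 1. Without both NeuNT/H1074R tumours that had high muscle genes, the macrophage list stood at −0.26 (camera adjusted p = 0.0769) and MHC class II at −0.21 (camera adjusted p = 0.216).

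Milk and secretory alveolar genes had wide differences in single genes. Of 23 members, 18 were lower in NeuNT/H1074R, by −0.72 on average and −0.12 at the median (camera adjusted p = 0.011; adjusted p = 0.804 with an estimated correlation). The caseins Csn1s1 and Csn1s2a differed by −2.88 ± 0.93 (SE) and −3.22 ± 1.39 (SE), the milk fat globule gene Btn1a1 by −2.40 ± 0.81 (SE) and Glycam1 by −2.03 ± 0.97 (SE). These genes varied between tumours of one genotype, as with Csn1s1, which ran from 6.11 to 11.28 in NeuNT/H1074R, and Glycam1 stood at −1.24 without NeuNT replicate 1. The call was lost without NeuNT replicate 4 (−0.59, camera adjusted p = 0.137) or NeuNT/H1074R replicate 4 (−0.52, camera adjusted p = 0.0815), and without both tumours with high muscle genes the mean was −1.16.

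Lists of basic cell functions were lower in the case of cholesterol synthesis, the cell cycle and the unfolded protein response, and higher in the case of glycolysis. Cholesterol synthesis genes were lower for 16 of 19 members, by −0.23 on average (camera adjusted p = 0.011; adjusted p = 0.834 with an estimated correlation), with Fdft1 at −0.42, Nsdhl at −0.34, Sc5d at −0.30 and the epoxidase Sqle at −0.65. The value of Sqle rested on NeuNT/H1074R replicate 4 (6.09, against 7.29 to 8.64 in the other tumours), without which it was −0.22, and it was −1.01 without NeuNT/H1074R replicate 3. Fdft1 stood at −0.27 without NeuNT replicate 4 and Nsdhl at −0.17 without NeuNT replicate 3. Cell cycle genes were lower for 34 of 40 members, by −0.17 on average (camera adjusted p = 0.0157; adjusted p = 0.834 with an estimated correlation), including the centromere histone Cenpa (−0.53), the mitotic kinase Aurkb (−0.46), Nusap1 (−0.41) and cyclin gene Ccne1 (−0.24). Without NeuNT/H1074R replicate 4, Cenpa stood at −0.34, Aurkb at −0.28 and Nusap1 at −0.24, and without NeuNT replicate 2 Cenpa and Aurkb stood at −0.81 and −0.72. Ccne1 stood at −0.16 and −0.15 without NeuNT replicates 3 and 4. Unfolded protein response genes were lower for 15 of 19 members, by only −0.09 on average (camera adjusted p = 0.0108; adjusted p = 0.804 with an estimated correlation), with the chaperone Hspa5 at −0.30 ± 0.12 (SE), Creld2 at −0.32, Manf at −0.24 and Sec61b at −0.23, whose probes differed in sign and whose value was −0.14 without NeuNT/H1074R replicate 2. Glycolysis genes were higher for 15 of 18 members, by 0.17 on average (camera adjusted p = 0.0345; adjusted p = 0.834 with an estimated correlation), with pyruvate kinase Pkm at 0.31 ± 0.11 (SE) and the phosphofructokinases Pfkl, Pfkp and Pfkm at 0.43, 0.49 and 0.45. Pfkm rested on NeuNT replicate 4, without which it was 0.12, and Pfkp stood at 0.80 without NeuNT replicate 1. The cholesterol call was lost without NeuNT replicate 3 (−0.12), NeuNT replicate 4 (−0.13), NeuNT/H1074R replicate 1 (−0.23) or NeuNT/H1074R replicate 4 (−0.10), and the mean was −0.35 without NeuNT/H1074R replicate 3. The cell cycle call was lost without NeuNT replicate 1 (−0.10), NeuNT replicate 3 (−0.11) or NeuNT replicate 4 (−0.08) and under a stricter filter on dim genes (camera adjusted p = 0.0573), and its mean turned to 0.04 without NeuNT/H1074R replicate 4. It stood at −0.40 without NeuNT replicate 2, −0.35 without NeuNT/H1074R replicate 3 and −0.29 with array weights. The unfolded protein response call was lost without NeuNT/H1074R replicate 3 (−0.05), and its mean was −0.05 with quantile normalization and −0.04 with centred arrays. The glycolysis call was lost without NeuNT replicate 2 (0.02), NeuNT/H1074R replicate 3 (0.12) or NeuNT/H1074R replicate 4 (0.14), with centred arrays (camera adjusted p = 0.0702), with no filter on dim genes (camera adjusted p = 0.0593) and with array weights (camera adjusted p = 0.107). Without both tumours with high muscle genes, glycolysis stood at 0.10 (camera adjusted p = 0.291), the unfolded protein response at −0.05 (camera adjusted p = 0.186), cholesterol synthesis at −0.40 and the cell cycle at −0.52.

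Skeletal muscle markers gave the smallest camera p. All 19 tested members had a higher mean in NeuNT/H1074R, by 0.77 on average (camera adjusted p = 1.05e-08, and adjusted p = 0.804 with an estimated correlation). The creatine kinase Ckm differed by 1.25 ± 0.47 (SE), the myosin heavy chain Myh1 by 1.23 ± 0.42 (SE), the troponin Tnnt3 by 1.06 ± 0.43 (SE) and the muscle enolase Eno3 by 0.59 ± 0.21 (SE). The list mean was 1.18 in NeuNT/H1074R replicate 1 and 1.05 in replicate 3, and between −0.53 and −0.20 in the other 6 tumours. The 4 genes named did not overlap between genotypes, as with Ckm, at 5.37 and 5.31 in NeuNT/H1074R replicates 2 and 4 and 4.82 to 5.12 in NeuNT. Ckm stood at 0.80 without NeuNT/H1074R replicate 1, and Myh1 at 0.80 without NeuNT/H1074R replicate 3. The call held whichever single tumour was left out, with means from 0.50 without NeuNT/H1074R replicate 1 to 1.02, but without both of these tumours the mean was 0.03 (camera adjusted p = 0.186), a fit chosen after the values had been seen.

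**Figure D2:**
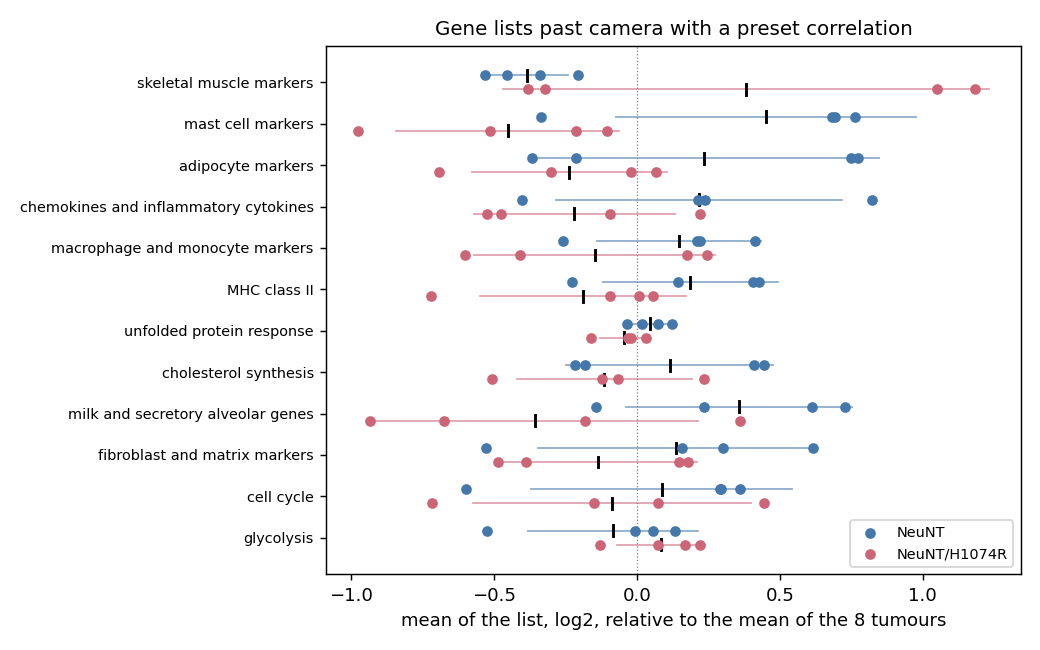
Mean log2 value of each gene list past camera with the preset correlation, per tumour and relative to the mean of the 8 tumours, with points for tumours, black ticks for the genotype means and lines for ± 1 SD (n = 4). The genotypes overlapped in all 12 lists, and the skeletal muscle mean was 1.18 and 1.05 in only 2 NeuNT/H1074R tumours.

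The lists closest to the mutated pathway did not separate the genotypes. Of 24 measured ErbB and PI3K pathway components, 12 were higher and 12 lower, with a mean log2 difference of 0.06 (camera adjusted p = 0.675; 0.01 to 0.12 when single tumours were left out), although the adaptor Grb7, a neighbour of Erbb2, differed by 1.10 ± 0.78 (SE), with 8.93 and 8.48 in NeuNT replicates 1 and 2 and 10.99 to 12.06 elsewhere. Without these tumours in turn Grb7 stood at 0.67 and 0.52, and without NeuNT replicate 3 at 1.71. Grb10 stood at 0.46, Erbb4 at 0.58 and the mTORC2 subunit Rictor at 0.20, and each moved with single tumours. Erbb4 was 0.16 and 0.33 without NeuNT/H1074R replicates 2 and 4, and 0.89 and 0.93 without NeuNT/H1074R replicates 1 and 3. Grb10 was 0.23 without NeuNT/H1074R replicate 4 and 0.69 without NeuNT replicate 2, and Rictor was 0.11 without NeuNT replicate 4 and 0.13 without NeuNT/H1074R replicate 3. FoxO target genes, which active PI3K signalling keeps low, had a mean of −0.03 (camera adjusted p = 0.878), within −0.08 to 0.01 when single tumours were left out, with Gadd45b at −0.70, Ccng2 at −0.32, Sesn3 at 0.54 (0.33 without NeuNT replicate 3) and Cited2 at 0.33 (0.18 without NeuNT replicate 4 and 0.22 without NeuNT/H1074R replicate 4). ERK output genes were higher for 15 of 19 members, by 0.22 on average, and did not pass (camera adjusted p = 0.0814), with Epha2 at 0.48, Phlda1 at 0.50, Dusp4 at 0.40 and Dusp5 at −0.54. The ERK mean rested on NeuNT replicate 2, without which it was 0.02 (camera adjusted p = 0.874), with Epha2 at 0.27, Phlda1 at 0.25, Dusp4 at 0.25 and Dusp5 at −0.88. The list passed camera without NeuNT replicate 1 (0.34), NeuNT replicate 3 (0.36) or NeuNT/H1074R replicate 1 (0.30), and not with an estimated correlation (adjusted p = 0.707, 0.713 and 0.769).

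Epithelial markers varied by tumour more than by genotype. Luminal markers had a mean difference of −0.05 (camera adjusted p = 0.878; −0.12 to 0.04 when single tumours were left out), with the tight junction gene Cldn4 at −1.22 ± 0.45 (SE), Spdef at 0.54, Ehf at 0.25 (0.14 without NeuNT replicate 2) and Cdh1 at 0.20 (0.10 without NeuNT replicate 3). Basal and myoepithelial markers had a mean difference of −0.27 (camera adjusted p = 0.149) that rested on NeuNT replicate 2, where the list mean was 1.72, and without it the difference turned to 0.26. The basal list passed camera without NeuNT replicate 1 (−0.58), NeuNT replicate 3 (−0.59) or NeuNT/H1074R replicate 3 (−0.59), and not with an estimated correlation (adjusted p = 0.761, 0.959 and 0.868), and its mean was −0.04 and −0.03 without NeuNT/H1074R replicates 2 and 4. In NeuNT replicate 2 the smooth muscle genes Tagln and Mylk stood at 10.35 (7.12 to 8.43 in the other 7 tumours) and 8.73 (5.76 to 6.34). Il17b stood at 9.55 there (4.41 to 5.83 in the other 7), while Lgr6, at 8.49, lay close to NeuNT replicate 4 (8.34). Squamous differentiation genes had a mean difference of −0.32 (camera adjusted p = 0.14) that rested on NeuNT replicate 4, where the list mean was 3.18, against −1.27 to 0.74 elsewhere. In that tumour the cornified envelope genes Sprr2h and Ivl, the transglutaminase Tgm3 and loricrin (Lor) stood at 8.97, 8.74, 8.68 and 5.90. Without it, squamous genes stood at 0.69 (camera adjusted p = 3.01e-05) and neutrophil markers, at −0.05 over all tumours (camera adjusted p = 0.878), at 0.50 (camera adjusted p = 0.000123). Neither passed with an estimated correlation (adjusted p = 0.878 for both). The squamous list passed camera in the other direction without NeuNT replicate 1 (−0.80), NeuNT replicate 2 (−0.65), NeuNT replicate 3 (−0.52) or NeuNT/H1074R replicate 1 (−0.62), each lost with an estimated correlation (adjusted p = 0.795, 0.913, 0.986 and 0.807). Without NeuNT/H1074R replicates 2 and 4 in turn, the squamous mean was −0.05 and −0.09 and the neutrophil mean 0.08 and 0.14.

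Correlations between tumours were as high across genotypes as within them. Pearson correlations over the tested genes averaged 0.933 within and 0.935 between genotypes (exact permutation p = 0.571, one-sided, 35 splits), and genotype took 12.2% of the variance against 14.3% expected with no effect (exact permutation p = 0.571). The closest pair was NeuNT/H1074R replicates 2 and 4 (r = 0.980), followed by NeuNT replicate 1 with NeuNT/H1074R replicate 2 (r = 0.971). These correlations are across genes, which are not independent replicates. The first component, with 34.3% of the variance, set NeuNT replicate 4 against NeuNT/H1074R replicates 2 and 4 and NeuNT replicate 1, and the second, with 22%, set NeuNT replicate 2 apart. Genotype accounted for most in the fourth, which held 11.1% of the variance, with 52.3% of it between genotypes (exact permutation p = 0.0571, 1 of 7 components).

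Genes beside Erbb2 stood apart in blocks that differed from tumour to tumour, an observation chosen after the values had been seen. Each value below is the log2 difference of a tumour from the median of the other 7, unless called a log2 signal. Such a difference cannot tell a tumour with a loss from one that lacks a rise shared by most of the others. NeuNT replicate 2 was low over Stac2, Fbxl20, Med1 and Cdk12 (mean −2.25, with an adjacent small RNA) and over Stard3 (−2.80), Pgap3 (−2.99), Mien1 (−2.58) and Grb7 (−3.02), while Erbb2 itself was at −0.63. NeuNT/H1074R replicate 4 was low over Fbxl20, Med1 and Cdk12 (mean −2.39, with the same small RNA). Fbxl20 was lower still in NeuNT replicate 4 (−2.51), where Med1 (−0.04) and Cdk12 (−0.16) lay near the median. The log2 signal of Fbxl20 was 7.36 to 8.36 in NeuNT replicates 2 and 4 and NeuNT/H1074R replicates 1 and 4, and 9.87 to 11.08 elsewhere. For Stard3 the log2 signal was 8.12 in NeuNT replicate 2 and 9.96 to 11.87 elsewhere. NeuNT/H1074R replicates 1 and 3 were high on the other side of Erbb2, over Psmd3 (2.58 and 2.47), Med24 (2.69 and 2.50), Msl1 (2.51 and 2.15) and Wipf2 (2.84 and 2.08). In replicate 3 a further run on the first side, from Plxdc1 to Fbxl20, was high (mean 1.56), and on the other side the high genes went on to Cdc6 (2.97), Rara (1.89) and Top2a (2.54), while in replicate 1 Cdc6 stood at 0.24. Cdc6 and Top2a also belong to the cell cycle list, so its mean in NeuNT/H1074R replicate 3 (0.45) includes values from this stretch. NeuNT/H1074R replicate 2 was high over Sp6, Scrn2, Lrrc46, Mrpl10 and Osbpl7 (mean 3.32), farther from Erbb2. In the other tumours these 5 genes stood between −1.02 and 1.20, both ends in Sp6. NeuNT replicates 1 and 3 were high over Fbxl20 (2.72 and 2.31), Stard3 (1.21 and 1.43) and Pgap3 (1.48 and 1.24).

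**Figure D3:**
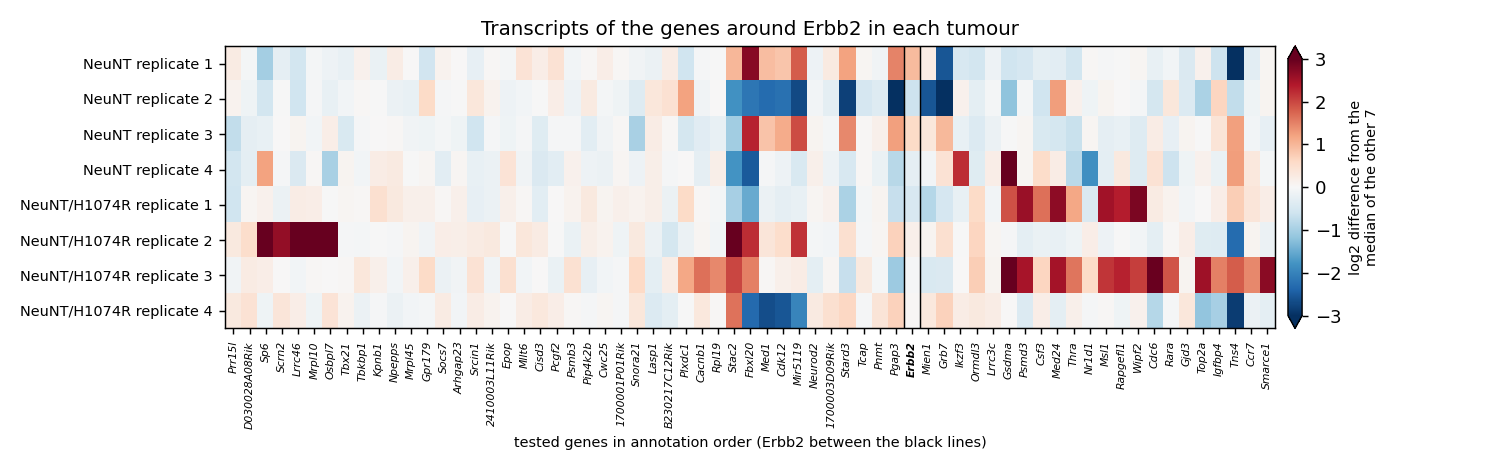
Log2 difference of each tumour from the median of the other 7 tumours for tested genes around Erbb2, in the gene order of assembly GRCm38.p6 and not to genomic scale. Red is higher and blue lower, with colours saturating at the ends of the bar. Runs of adjacent genes stand apart in some of the tumours, such as Sp6 to Osbpl7 in NeuNT/H1074R replicate 2 (mean 3.32).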

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

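The test on skin genes in this part was set before its result was seen, though the hair follicle and skin gene lists were chosen after the squamous pattern had been noticed. In each genotype the tumour farthest from the other 3 was compared with the spread of its group by Dixon's ratio, for the named genes and described lists. This singled out 14 values in 214 groups, against 10.7 expected by chance.

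NeuNT replicate 4 stood above the other NeuNT tumours in Sprr2h (8.97 against 3.74 to 4.06), Ivl (8.74 against 4.63 to 4.96) and Tgm3 (8.68 against 4.89 to 4.97). Of 27 squamous genes, 25 were highest in this tumour, with a median log2 difference of 3.72 from the other 7, and so were 20 of 21 hair follicle genes (median 3.02), such as the inner root sheath keratin gene Krt73 (10.86) and Tchh (10.76). Next came NeuNT/H1074R replicate 1 for Krt73 (7.416) and Tchh (7.425), against 4.70 to 5.49 and 3.35 to 4.94 in the remaining tumours. For Krt28 (6.489) and Dlx3 (7.74) it was NeuNT/H1074R replicate 3, while Krt33b was raised in neither (4.393 and 4.726). A piece of skin carried in the sample was tested with sebaceous gland and melanocyte genes, which skin also holds. Their median difference over 11 genes was 0.152 (95% bootstrap interval over these genes −0.524 to 0.348), under the 0.5 set as the bound. Even so, 4 of the 11 were highest in this tumour (1.38 expected by chance). This cannot decide against skin, because markers such as Awat1, Awat2, Elovl3, Dgat2l6, Tyr, Tyrp1 and Oca2 were not among the tested genes. Of the 6 sebaceous genes that were, 1 is also an adipocyte marker and 2 lay above the median of tested genes in the other tumours. Carried skin and squamous and hair-type differentiation of the tumour cells both stay open, and no biological explanation was tested because no label sets this tumour apart.

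NeuNT replicate 2 was above its group in Il17b (9.55 against 4.95 to 5.57), a basal marker here. The same tumour was below its group in the ERK phosphatase Dusp5 (7.16 against 8.38 to 8.63), in Ccng2 (7.15 against 7.76 to 7.82) and in the mean of the cell cycle list (−0.60 against 0.29 to 0.36). NeuNT replicate 3 was below its group in mast cell markers (list mean −0.34 against 0.68 to 0.76).

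NeuNT replicate 4 was also below its group in Pfkm (5.80 against 7.08 to 7.13) and in ErbB and PI3K pathway components (list mean −0.18 against 0.02). Among NeuNT/H1074R tumours, Pfkm was low in replicate 1 (6.78 against 7.36 to 7.40), Pfkp high in replicate 4 (10.1 against 9.60 to 9.66), Ciita low in replicate 3 (5.94 against 6.43 to 6.50) and Tgm3 low in replicate 2 (4.14 against 5.06 to 5.23).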

How the results depend on the processing

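The fit without both tumours with high muscle genes, and the estimated correlation without single tumours, were chosen after the data had been seen; the other alternatives were planned. The count of genes past the threshold was 0 in limma under every alternative run, with 635 genes at an unadjusted p under 0.05 in the reported fit and 714 in the ordinary two-sample test, which also gave 0, and 0 of the 84 named genes passed under any (lowest adjusted p 0.374). The log2 differences of 47 of these 84 genes moved by over 1.5 times without some single tumour. The count of gene lists, 12 as reported, ran from 8 to 20 when single tumours were left out, the 20 without NeuNT replicate 1, and from 11 to 17 under the other camera settings, 12 without both muscle-high tumours. It was 0 with an estimated correlation, 0 with fry and 0 with the exact permutation of list means, whose smallest possible p of 0.0286 leaves little room after adjustment over 39 lists. With an estimated correlation it was also 0 without each of the tumours (lowest adjusted p = 0.213). The variance settings of the gene fit were not varied for the lists, and camera was run without an intensity trend throughout. Leaving out single tumours turned the sign of 11 log2 differences, with ranges of −0.49 to 0.027 for Erbb2, −0.98 to 0.013 for Mylk, −1.29 to 0.086 for Ivl, −0.40 to 0.037 for the cell cycle, −0.080 to 0.0084 for FoxO targets, −0.22 to 0.27 for the interferon response, −0.22 to 0.27 for the estrogen response, −0.12 to 0.038 for luminal markers, −0.59 to 0.26 for basal markers, −0.80 to 0.69 for squamous genes and −0.37 to 0.50 for neutrophil markers. The signs of some list means near 0 also turned, to 0.00040 for FoxO targets with quantile normalization, to 0.016 for FoxO targets, 0.0024 for luminal and 0.0035 for neutrophil markers with centred arrays, and for the estrogen response to 0.019 with array weights and 0.013 without both muscle-high tumours. The cause was not tested. The list median and camera's direction differed in sign for 1 list and the mean and that direction for 4. No paired analysis was possible because the tumour numbers in the labels are not shared between the genotypes.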

Other observations

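The tests on the genes beside Erbb2, on ERK output and on the muscle genes by genotype were chosen only after the values had been seen; the test on the second muscle list and the counts over other splits were set before their results. The 27 lists that did not pass camera had adjusted p between 0.0553 and 0.878, among them B and plasma cell markers (mean log2 difference −0.21), endothelial markers (−0.11), hypoxia response (0.09), MYC targets and ribosome biogenesis (0.05), and oxidative phosphorylation (−0.04). In the Wnt list, 19 of 24 members were lower in NeuNT/H1074R, by −0.18 on average, while Rnf43, a ubiquitin ligase that dampens Wnt signalling, was higher by 0.48 ± 0.11 (SE), the 1 member past the threshold when adjusted over the list alone (limma, adjusted p = 0.0492). T cell markers were lower for 17 of 19 members (mean −0.20, camera adjusted p = 0.0553), and interferon response genes stood at 0.04 (camera adjusted p = 0.578), with list means from −0.81 to 0.56 in single NeuNT tumours. The T cell list passed camera without NeuNT replicate 1 (−0.29), NeuNT replicate 3 (−0.31), NeuNT/H1074R replicate 2 (−0.23) or NeuNT/H1074R replicate 4 (−0.21), while its mean was −0.03 without NeuNT replicate 4 (camera adjusted p = 0.984) and −0.13 without NeuNT/H1074R replicate 3. The interferon list passed as higher without NeuNT replicate 3 (0.24) or NeuNT/H1074R replicate 1 (0.27) and as lower without NeuNT replicate 1 (−0.22), and its mean was −0.11 and −0.04 without NeuNT/H1074R replicates 2 and 4. Epithelial to mesenchymal transition regulators stood at −0.19 (camera adjusted p = 0.354) and passed without NeuNT replicate 1 (−0.31) or NeuNT/H1074R replicate 1 (−0.37), while their mean was −0.07 without NeuNT replicate 2 (camera adjusted p = 0.911) and −0.06 without NeuNT/H1074R replicate 4 (camera adjusted p = 0.805). The estrogen response, at −0.06 (camera adjusted p = 0.52), turned to 0.27 and passed without NeuNT replicate 2. None of these calls held with an estimated correlation (lowest adjusted p = 0.615).

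NeuNT replicate 2 combined several features that were not seen together in the other tumours. Its list means were highest of the 8 for several lists, among them basal markers (1.72), the estrogen response (1.02), adipocyte markers (0.77), fibroblast markers (0.62), endothelial markers (0.49), epithelial to mesenchymal transition regulators (0.46) and Notch pathway genes (0.44). Lists in which it was lowest included neutrophil markers (−0.95), ERK output (−0.71), glycolysis (−0.52) and the hypoxia response (−0.48). It also had the lowest Erbb2 value, 8.73. These are values of 1 tumour and were not tested.

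Of 29 runs of at least 4 adjacent genes that stood apart by 1 or more in a tumour, 9 lay within 40 genes of Erbb2, whereas a shuffled gene order gave at most 1 run in all. By the starts of their symbols, 19 runs held largely genes of 1 family, such as keratins or kallikreins, 13 of them in NeuNT replicate 4, and of the other 10, 7 lay within 40 genes of Erbb2. The median SD of the 41 genes centred on Erbb2 was 0.737, against a median of 0.248 over windows (percentile 99.44), so most windows spread less. The window was picked because its genes stood apart, so the percentile restates that choice. It cannot decide against signal or scale differences of whole arrays. Copy number changes around the receptor gene may underlie these blocks, a hypothesis found and tested on the same data with no DNA measured: next neighbours in that window moved together across the 8 tumours (mean r 0.487, against a median of 0.122 over 15790 windows, percentile 99.39). Windows elsewhere reached 0.683, and coregulated neighbours stay open. Runs of any kind occurred in 4 of 4 NeuNT/H1074R and 2 of 4 NeuNT tumours within 40 genes (Fisher's exact p = 0.429, two-sided). Those not of 1 family occurred in 4 and 1 (Fisher's exact p = 0.143), and in 3 and 1 within 20 genes (Fisher's exact p = 0.486). These counts depend on the rule for a run. Neurod2, Tcap, Pnmt, Erbb2 and Ormdl3 stood apart by less than 1 in every tumour, so Stard3, Pgap3, Mien1 and Grb7 could enter no run. NeuNT replicates 1 and 3 had high genes near Erbb2 in no such run. Genotype took 13.8% of the variance in the 41-gene window (exact permutation p = 0.486, highest other split 31.0%), so an effect of genotype cannot be told apart from none with 4 tumours each.

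Skeletal muscle genes were high in NeuNT/H1074R replicates 1 and 3. The list mean lay above all NeuNT tumours in 2 of the 4 NeuNT/H1074R tumours, which restates the pattern and leaves an effect of genotype open. Muscle tissue carried in the samples could be the source: in a second list of 18 muscle genes, none in a fixed list or above the median of tested genes in the other tumours, 13 (72.2%) were higher in both tumours than in each of the other 6, against 3.57% by chance. That share lay between the bounds set for and against this explanation, so muscle tissue cannot be told apart from muscle-type expression in some tumour cells. The abundant muscle gene Ckm stood at 7.58 and 6.71 in these tumours and at 4.82 to 5.37 elsewhere, though above all NeuNT tumours in replicates 2 and 4 too. NeuNT/H1074R replicates 1 and 3 also had the highest squamous list means after NeuNT replicate 4. They stood at 0.74 and 0.43, against 3.18 in that tumour and −1.27 to −0.43 in the rest. A shared source of the muscle and squamous signal was not tested.

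The mean of the ERK output list followed Erbb2 across the 8 tumours (Pearson r = 0.794, exact permutation p = 0.0185, and Spearman rho = 0.857, exact permutation p = 0.0107), and r was 0.826 without NeuNT replicates 1 and 2, the tumours farthest from the median Erbb2 value. This was 1 of 39 lists set against Erbb2, and neither coefficient passed after adjustment over them (exact permutation, adjusted p = 0.325 and 0.209). After the genotype means were subtracted, r was 0.949. The hypothesis that ERK output follows the Erbb2 transcript may be worth a test in other tumours, but these 8 do not decide it. The relation with p53 targets and senescence was negative and had the smallest exact permutation p of the 39 lists, 0.00687 (r = −0.852, rho = −0.881, exact permutation adjusted p = 0.268 and 0.209, r = −0.762 without the same 2 tumours, r = −0.861 after the genotype means were subtracted). Basal markers (r = −0.755, exact permutation p = 0.0299) and Wnt genes (r = −0.734, exact permutation p = 0.0378) were negative too. Neither passed after adjustment (exact permutation, adjusted p = 0.325 for both).

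The genotypes were compared with the other splits of the 8 tumours into 4 and 4, which make 35. With 0 genes past the threshold in limma, all 35 splits gave as many by necessity, so this count says nothing about chance, and the highest other split gave 146. At an unadjusted p under 0.05, 15 of the 35 gave at least the 635 genes of the real split, and the highest gave 2910. For the lists, 25 of the 35 gave at least the 12 of the real split, and the highest gave 22. Chance is therefore excluded for neither of these counts. The split with 146 and 2910 genes set NeuNT replicates 1 and 2 and NeuNT/H1074R replicates 2 and 4 against the remaining tumours. It was the highest of the 35 and followed the sign of the first principal component. Its counts therefore do not test whether the samples hold a structure apart from genotype.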
